A study of Homo sapiens with 3 samples.

How the data were processed

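RNA from 3 samples of normal human breast tissue was measured on Affymetrix Human Gene 1.0 ST arrays, which carry short probes along each transcript, grouped into probe sets. Per the labels' protocols, total RNA was isolated from fresh tissue, 1 ng of it was amplified, 4 µg of the amplified cDNA went into a further amplification, and the product was labelled with biotin and hybridized to 1 array per sample. The labels number the samples 1 to 3 and put them in 1 group. They do not state whether the samples came from separate donors, so the spread between them measures these samples and may be in part technical.

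The deposited values are log2 expression levels, with 1 value per probe set and array. Background correction and normalization by the authors used GCRMA in Partek, per the submitters' processing notes, which name both tools without versions or settings. GCRMA corrects each probe for unspecific binding predicted from its sequence, brings the arrays to a common distribution and summarises the probes of a set on the log2 scale. The log2 scale was inferred from the values, which ran from 0.945 to 14.53 across the arrays. Array medians were 5.69, 5.68 and 5.72 for samples 1 to 3, and no further scaling was applied. Because the authors had already brought the arrays to like distributions, a difference in the overall amount of RNA between samples cannot be seen in these values. GCRMA also pulls weak signals toward a floor, so ratios of genes near background are compressed or unstable. Genome build and probe annotation of the original processing were not given in the sources used here.

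Gene names came from the platform annotation. Of 33297 probe sets, 19460 were listed with 1 gene symbol and 1754 with several, and 12083 were unnamed here. Probe sets with several symbols or unnamed were left out. Symbols were updated by gene identifier through a RefSeq gene table of assembly GRCh38.p14, used for names only, in which 19429 of the 19460 probe sets matched. This gave 18417 genes. For the 769 genes with several probe sets, the probe set with the highest mean over the 3 samples was used, with the median of the probe sets as an alternative. Loricrin was first missed because its older symbol is shared with another gene. It was added to the epidermis list by hand after its values had been seen, which lowered the median of that list in sample 2.

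A gene was taken as above background on an array where its level exceeded the 95th percentile of 341 olfactory receptor genes on that array, since olfactory receptor RNA is largely restricted to the olfactory epithelium. The limits were 4.91, 4.65 and 4.71 on the log2 scale. Levels below the limit are bounds: where the lowest sample lay under its limit, a ratio was computed with the limit in its place and is given as "at least". Probes differ in affinity, so each gene was compared with itself across samples and not with other genes.

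With 1 group there was no test between groups, and none exists between single samples. The question a single group can answer per gene, whether it varied more than genes of like level, was tested with limma. The residual variance of an intercept fit (2 degrees of freedom) was divided by the prior variance from squeezeVar with an intensity trend and a robust prior. Upper-tail p-values of this ratio were adjusted with the Benjamini-Hochberg method at 0.05 over 15029 genes above background on at least 1 array. For 32 lists of named genes and 8 families defined by symbol, fixed before the data were examined, the median deviation of the members from their own 3-sample mean was computed per sample, over members above background on at least 1 array and for lists with at least 3 of these. Each median was set against 10000 random lists of the same size drawn within 20 bins of mean level. Such a percentile describes these arrays and is not a p-value. The number of arrays limits the precision of every value.

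Named genes followed a rule fixed before the data were examined: per list the 2 members of highest mean and the 1 of largest SD, each measured receptor and reference gene, the 15 genes of largest and the 10 of lowest SD among genes above background on all 3 arrays, and genes passing the variability test. It took 139 genes. Other genes named, including further list members, were chosen after their values were seen. Sex-linked genes that would reveal a donor trait and genes whose level is mainly set by a common deletion or haplotype, 46 in all, were neither named nor entered in the variability test.

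The variability test was tested on simulated data of 15029 genes. It called 0 genes where none had been changed. Among 200 genes with a spread 3, 6 or 12 times that of the others it called 0, 8 and 104, with 0, 0 and 1 unchanged genes called. In 5 simulated draws of 2 samples with no changed gene it called 0 genes in 4 draws and 1 gene in 1 draw. The degrees of freedom given to the prior variance were 4.19 to 6.48 in these draws. In the data they were 153 without sample 3 and 11.3 without sample 2, so the draws give no false call rate for those runs. The random-list step, tested on 100 lists of 10 genes, placed 9 unshifted lists outside the central 95% and all 100 lists shifted by 1 on the log2 scale above it. Alternatives were other background limits, the probe set rule, quantile normalization, median centring, filters, settings of the variance prior, means in place of medians, linear-scale means and each sample left out in turn. Setting levels under the limit to the limit, and taking the second lists of the closing section over all measured members, were added after the data were seen. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.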

Results

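Expression was measured in 3 samples of normal breast tissue, which the series describes as controls. The labels give 1 group, so the question that can be asked is which genes and cell type markers were present in normal breast tissue and how far single samples differed. Values are log2 levels, given as mean ± SD with n = 3 or per sample, and a difference of 1 is a 2-fold difference. Samples 1, 2 and 3 carry the numbers of the labels and have no order.

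Most markers of the cell types of the breast were above background in all 3 samples, where 73.0% of all genes were. Markers of luminal and general epithelium (11 of 11 measured), secretory luminal cells (12 of 12), basal and myoepithelial cells (8 of 8), adipocytes (12 of 12), fibroblasts (12 of 12), blood endothelium (12 of 12), lymphatic endothelium (7 of 7), pericytes and smooth muscle (10 of 10) and macrophages (11 of 11) were above the limit on every array, as were 10 of 11 markers of hormone-sensing luminal cells. KRT8, a keratin of luminal cells, was at 10.35 ± 0.37 (SD, n = 3). ACTG2, a smooth muscle actin of myoepithelial cells, was at 10.65 ± 0.23, the fatty acid binding protein FABP4 at 11.20 ± 0.80, the matrix proteoglycan DCN at 12.11 ± 0.12 and the endothelial adhesion molecule PECAM1 at 11.33 ± 0.69.

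Lists of other tissues, of lactation and of some other cell types were less complete. Of 6 milk protein genes, 1 was above background on all 3 arrays, XDH, at 5.52 ± 1.07. CSN3, a casein, was above the limit on 1 array. The hepatocyte list had 2 of 8 members above background on all arrays, the neuron list 4 of 7, melanocytes 0 of 4, Schwann cells and nerve 2 of 4, mast cells 2 of 3, red blood cells 3 of 5, and taste receptors 4 of 27. T and NK cell markers were above background for 9 of 12 members and those of B and plasma cells for 7 of 9. Both lie close to the share of all genes, 73.0%. JCHAIN, the joining chain of secreted antibodies, was at 11.02 ± 0.71. Keratin-associated proteins, mostly genes of hair, had 32 of 67 members above the limit, and 11 of the 341 olfactory receptors were above it on all 3 arrays. With the 99th percentile as the limit, the counts were 0 for milk proteins, 2 for B and plasma cells and 1 each for hepatocytes, neurons, mast cells, red blood cells, taste and olfactory receptors. Without sample 3 the melanocyte count was 1.

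Across all genes, 13453 of 18417 (73.0%) were above background on all 3 arrays, 15052 on at least 1 and 3365 on none. Per array the count was 13986, 14467 and 14333. With the limit taken from 3 gene families together the count on all arrays was 9545, and with the 75th percentile it was 15639.

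The samples correlated across genes with Pearson's r of 0.965 (samples 1 and 2), 0.944 (1 and 3) and 0.955 (2 and 3), with Spearman's rho of 0.962, 0.936 and 0.952. Genes are not independent replicates, and r over genes above background on all arrays was lower, at 0.949, 0.893 and 0.924. The median SD of a gene was 0.27 and the median range 0.51. Among genes above background on at least 1 array, 2170 (14.4%) had a range of over 2-fold and 72 of over 8-fold. Of the 2170, sample 3 was highest for 997, sample 2 for 646 and sample 1 for 527. Without sample 3 the count was 543 and without sample 1 it was 1136.

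Lists of genes of general cell function were not tested against each other for spread. Median SDs of the reference, ribosomal protein and interferon response lists lay inside the central 95% of random lists of like level. That of the proteasome list lay below it, at 0.18 against a lower end of 0.19. The respiratory chain list also lay below, at 0.206 against a lower end of 0.216. The 10 measured reference genes had a median SD of 0.27, as did all genes above background on at least 1 array, with ACTB at 13.03 ± 0.19, B2M at 11.88 ± 0.10, YWHAZ at 10.18 ± 0.28 and PGK1 at 7.97 ± 0.08. GAPDH had the widest SD of these genes (12.32 ± 0.53), with 11.83 in sample 2 and 12.88 in sample 3, followed by TBP (7.71 ± 0.41) and TFRC (8.10 ± 0.40). Ribosomal protein genes, above background for 63 of 64 members, had a median SD of 0.21. Of these, 49 were lowest in sample 2 and 47 highest in sample 3, with median deviations of −0.17 and 0.16, which were −0.0964 without sample 3 and 0.0820 without sample 2, and 0.0793 in sample 3 after quantile normalization. Proteasome genes, 34 of 36 above background, had a median SD of 0.18. The interferon response list, 12 of 12 above background, had a median SD of 0.23, and IFI6 was at 7.77 ± 0.01. Among the 10 genes of lowest SD were the phospholipase PLCG2 at 12.34, WSB2 at 8.36 and MINK1, a kinase, at 7.55, each with a range of at most 1.01-fold.

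Epidermal genes stood highest in sample 2. All 8 members of the epidermis list were highest there, and their median deviation was 3.85, against −2.02 in sample 1 and −1.74 in sample 3 (−0.44 and 0.44 without sample 2). KRT10 and KRT1, the keratin pair of differentiating keratinocytes, were at 12.38 and 12.02 in sample 2. In sample 3 they were at 5.54 and 5.61, and in sample 1 below the limit, at least 177-fold and 139-fold lower than in sample 2. DSG1, a desmosomal cadherin, was at 11.33 in sample 2 and FLG, the filaggrin precursor, at 10.62. Of the 8 genes, 2 were above background on all 3 arrays, 5 without sample 1 and 0 with the 99th percentile limit. DSC3, a desmocollin on the basal list, was at 9.99 in sample 2, 6.89 in sample 1 and 6.32 in sample 3, and the basal keratin KRT5 at 11.77, 10.51 and 9.91. The melanocyte gene TYRP1 was at 7.28 in sample 2 and below the limit in the others.

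Adipocyte markers also stood highest in sample 2, for 11 of 12 genes, with median deviations of −0.39, 1.02 and −0.60 in samples 1, 2 and 3. Without sample 2 those of samples 1 and 3 were 0.12 and −0.12. Leptin (LEP) was at 6.46, 9.45 and 8.35. FABP4 was at 11.67, 11.66 and 10.27. Immediate early genes, transcription factors and regulators induced within minutes of a stimulus, were highest in sample 2 for 11 of 11 genes and lowest in sample 3 for 10, with median deviations of 0.03, 1.01 and −1.21. Without sample 2 that of sample 3 was −0.41, and without sample 3 that of sample 2 was 0.49. FOSB was at 6.80, 10.49 and 6.79 and the phosphatase DUSP1 at 11.85, 12.55 and 10.38. The inflammatory and acute phase list had a median deviation of 0.88 in sample 2 (0.51 without sample 3) and −0.77 in sample 3 (−0.22 without sample 2), with the serum amyloid gene SAA1 at 6.94, 10.19 and 7.14.

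**Figure D1:**
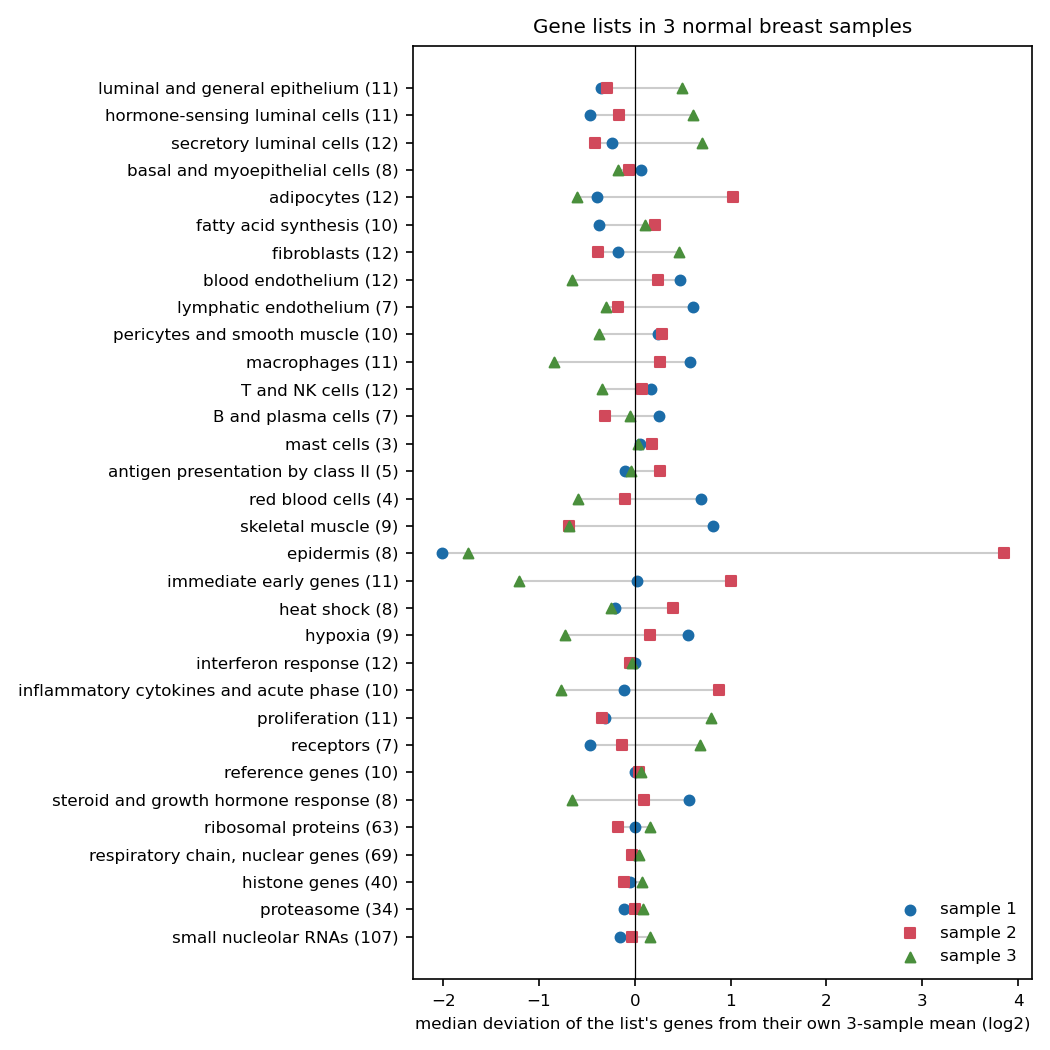
Each line is a gene list, with the number of its genes above background on at least 1 array in parentheses. The horizontal axis gives the median deviation of these genes from their own 3-sample mean on the log2 scale, and points mark samples 1 (circle), 2 (square) and 3 (triangle). The epidermis list reaches 3.85 in sample 2, while the reference genes lie near 0, at 0.06 in sample 3. Not shown are lists with under 3 such genes and the olfactory receptor, taste receptor, keratin-associated protein, neuron and hepatocyte lists. Of these, the taste receptors had 0.64 in sample 3.

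Most epithelial, fibroblast and proliferation markers stood highest in sample 3. This held for 9 of 11 luminal and general epithelial genes, 10 of 11 hormone-sensing luminal genes, 8 of 12 secretory luminal genes, 9 of 12 fibroblast genes and 11 of 11 proliferation genes above background on at least 1 array. Median deviations in sample 3 were 0.49, 0.61, 0.70, 0.47 and 0.79 for these lists, with 0.30 for fibroblasts without sample 2. EPCAM, an epithelial adhesion molecule, was at 6.25, 7.54 and 10.49 in samples 1, 2 and 3, an 18.9-fold range. PROM1, a surface protein of luminal progenitors, was at 6.92, 6.56 and 9.81, the collagen gene COL1A1 at 9.10, 9.82 and 12.11, and the mitotic cyclin CCNB1 at 5.12, 5.52 and 7.36. The basal list, with deviations of 0.07, −0.06 and −0.18, lay inside the central 95% of random lists in every sample.

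Markers of vessels and macrophages were lowest in sample 3. This held for 12 of 12 blood endothelial genes, 11 of 11 macrophage genes and 8 of 10 pericyte and smooth muscle genes, with median deviations there of −0.66, −0.84 and −0.38, and −0.52 for macrophages without sample 1. The von Willebrand factor gene VWF was at 10.38, 10.38 and 8.34, and the scavenger receptor CD163 at 10.46, 10.29 and 8.12. Lymphatic endothelial genes had a median deviation of 0.61 in sample 1 (0.29 without sample 3) and −0.30 in sample 3 (−0.0173 without sample 1). Hypoxia genes were lowest in sample 3 for 8 of 9 members, among them ADM (adrenomedullin) at 10.72, 10.15 and 7.59. The steroid and growth hormone response list had a median deviation of −0.66 in sample 3 (−0.38 without sample 1), with ZBTB16 at 10.10, 9.52 and 7.30. Haemoglobin beta (HBB) was at 8.46 ± 2.05, with 10.19 in sample 1 and 6.19 in sample 3.

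Skeletal muscle genes stood highest in sample 1 for 8 of 9 members, with a median deviation of 0.81, against −0.69 and −0.68. With levels under the limit set to the limit, a setting chosen after seeing the data, these were 0.57, −0.29 and −0.44. Without sample 1 the medians of samples 2 and 3 were 0.23 and −0.23. TTN, the giant spring protein of the sarcomere, was at 9.24, 5.84 and 5.26, and ACTA1, skeletal actin, at 8.76, 8.11 and 6.98.

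The 7 measured receptors of a list built around those used to class breast tumours were above background on all arrays. ESR1, the estrogen receptor, was at 6.21 ± 0.20, PGR, the progesterone receptor, at 6.17 ± 0.49, and ERBB2 at 7.34 ± 0.59. EGFR was at 8.68 ± 0.09, ERBB3 at 7.23 ± 0.73, ERBB4 at 6.67 ± 1.15 and PRLR, the prolactin receptor, at 6.60 ± 1.10. Of the 7 receptors, 6 were highest in sample 3, and 3 of them (ESR1, PGR and PRLR) also belong to the hormone-sensing list.

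**Figure D2:**
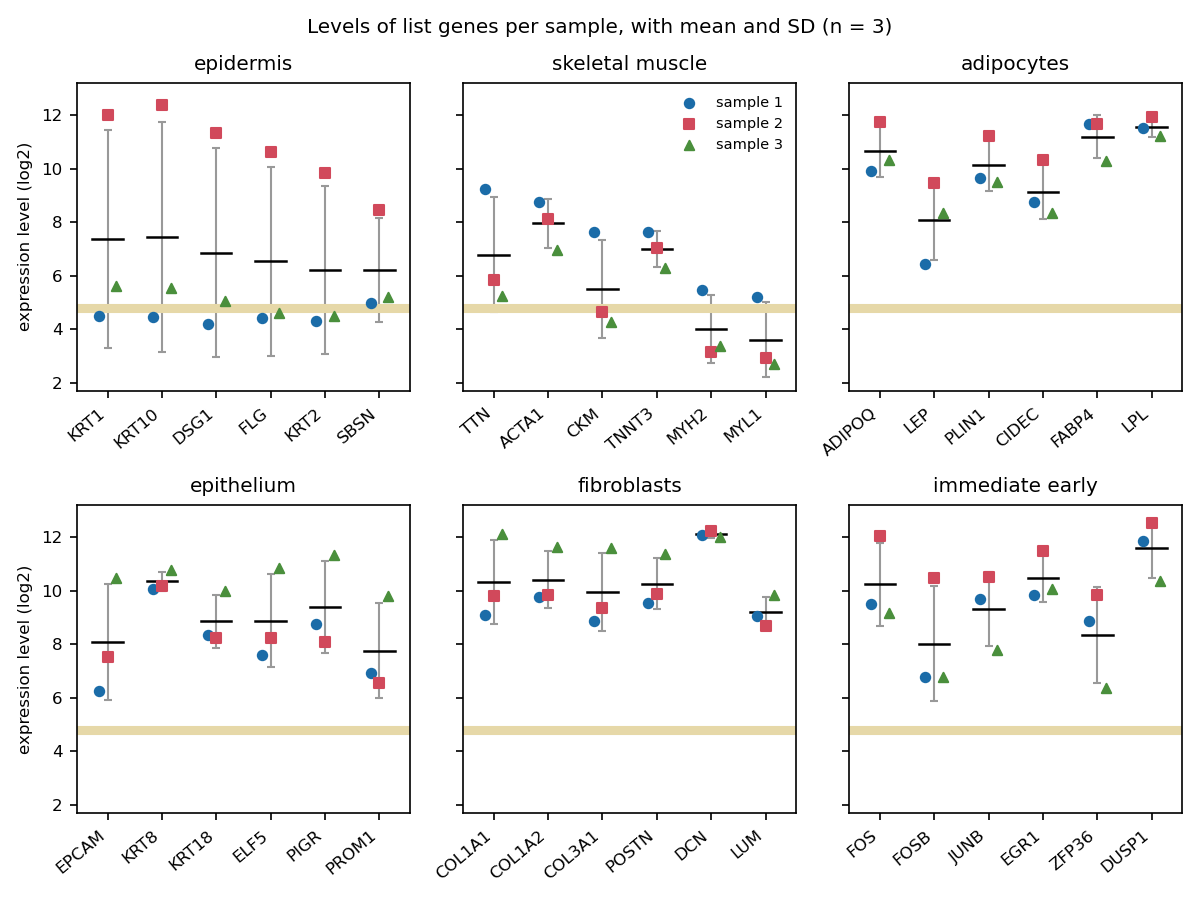
Log2 levels of 6 genes from each of 6 groups per sample (circle, 1; square, 2; triangle, 3), with the mean as a black line and the SD (n = 3) as a gray bar; the epithelium panel mixes luminal and secretory genes, and the tan band spans the background limits of the 3 arrays (4.65 to 4.91). KRT10 lies at 12.38 in sample 2 and near the band in the others, and DCN lies close to 12.11 in all 3 samples.

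None of these genes passed the test for wider variation than genes of like level. The test detects little with 3 samples: of 200 simulated genes with 6 times the spread of the others it called 8. Failing it therefore does not show that a gene varied like the others. Of 15029 genes tested with limma, 0 had an adjusted p under 0.05, the smallest being 0.136 (KRT10 and KRT1), and 842 had an unadjusted p under 0.05 where 751 are given by chance at that level. Without sample 3, 186 genes passed, of which 159 were higher in sample 2 and 27 in sample 1, and without sample 2, 22 passed. Those counts set 1 sample against 1 other and are no test between groups. The degrees of freedom of the prior were 153 without sample 3 and 11.3 without sample 2. With all samples they were 4.85, so the test was more lenient in those 2 runs. The largest SDs among genes above background on all 3 arrays, after EPCAM, TTN, FOSB and HBB, were those of the endocytic receptor LRP2 (4.93, 6.14 and 8.81) and GALNT15, an O-glycosylation enzyme (9.91, 9.40 and 6.26). The plasma glutathione peroxidase GPX3 was at 11.47, 11.16 and 8.01. Of 111 medians of list and sample, 61 lay outside the central 95% of random lists of like level, where 5.55 are given by chance, although the members of a list do not vary independently.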

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

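Each result was recomputed with 1 choice changed at a time. Setting levels under the background limit to the limit was the 1 alternative here chosen after seeing the data. The count of genes above background stayed within 1.5 times of 13453 under each alternative run, from 9545 to 15639. The count of genes with a range of over 2-fold ran from 543 (without sample 3) to 1511 (without sample 2) with a sample left out, since the range of a pair of samples is narrower. The variability test called 0 genes under each other filter, scaling and prior run, though it finds few genes even at 6 times the spread. With a sample left out it called 0 (without sample 1) to 186 (without sample 3), where the degrees of freedom of the prior also differed. Pearson's r was 0.949, 0.893 and 0.924 when genes under the limit were left out. Of 488 recomputed list deviations, 473 kept their sign and moved by less than the spread between samples, 2 moved by more and 13 changed sign. These 15 were in runs with a sample left out, where the mean is taken over the remaining pair. The spread is the SD of a list's own 3 deviations, so it grows with them and is a loose bound. Luminal and general epithelium in sample 1, for example, went from −0.35 to −0.0304 without sample 3 and stayed within it. Of the 122 values with a sample left out, 53 were smaller in size than the value of all samples by over 1.5 times, in part because a sample weighs more in the mean of a pair. The lowest and highest values with a sample left out were, for sample 2, −0.43 and 0.0304 for luminal and general epithelium, −0.41 and 0.20 for hormone-sensing luminal cells, −0.45 and 0.0546 for fibroblasts, −0.0661 and 0.47 for blood endothelium, −0.29 and 0.0173 for lymphatic endothelium, −0.0977 and 0.52 for macrophages, −0.56 and 0.23 for skeletal muscle, −0.16 and −0.0708 for neurons, −0.64 and 0.13 for proliferation and −0.0605 and −0.0156 for histone genes. For sample 1 they were −0.51 and 0.0658 for secretory luminal cells, −0.72 and 0.12 for adipocytes, −0.0250 and 0.25 for pericytes and smooth muscle and −0.52 and 0.17 for taste receptors, and for sample 3 they were −2.84 and 0.44 for epidermis. Of 280 recomputed counts of list members above background, 267 stayed within 1.5 times, and 11 of the other 13 were under the 99th percentile limit. The 139 gene levels moved by less than their SD with means taken on the linear scale. With 3 samples and the ranges seen here this could not come out otherwise, so it is no test of the levels. Signal over background limits the genes near the limit, where a ratio is a bound. No paired analysis was possible because the labels give 1 group.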

Other observations

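Some genes outside the lists, chosen after their values were seen, differed widely between samples. The B cell attractant chemokine CXCL13 was at 8.99 in sample 3 and below the limit in the others (3.49 and 3.38), at least 17.0-fold lower. CYP24A1, the enzyme that inactivates vitamin D, was at 7.72 in sample 3 and below the limit in samples 1 (3.55) and 2 (3.75). SELE, the E-selectin of activated endothelium, was at 8.26 in sample 2 and below the limit in samples 1 (4.73) and 3 (4.55). PLIN2, a lipid droplet coat protein, was at 11.54, 9.59 and 7.93 in samples 1, 2 and 3. Of the list members, the small nucleolar RNA SNORD14E was at 7.51 in sample 2 and below the limit in the others (3.33 and 3.26), while HSPA8, whose introns hold it, was at 11.62, 11.98 and 12.38.

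Small nucleolar RNAs, above background on all arrays for 78 of 173 members, had median deviations of −0.15, −0.03 and 0.16 in samples 1, 2 and 3, and over all measured members −0.0966 in sample 1 and 0.0931 in sample 3. With a sample left out they were as small as −0.0803 in sample 1 (without sample 3) and 0.0758 in sample 3 (without sample 1). Heat shock genes (8 of 8) had 0.40 in sample 2 (0.25 without sample 3) and fatty acid synthesis genes (9 of 10) −0.37 in sample 1 (−0.23 without sample 2). Antigen presentation by class II (5 of 5) had 0.27 in sample 2, where all 5 were highest, which lay inside the central 95% of random lists. Respiratory chain genes (65 of 74) had a median of 0.04 in sample 3, inside the central 95%, and histone genes (35 of 59) had −0.05, −0.11 and 0.07. The taste receptors had 0.64 in sample 3, but 0.41 without sample 1, 0.20 over all measured members and 0.43 with levels under the limit set to the limit. T and NK cell markers had −0.34 in sample 3, B and plasma cell markers −0.31 in sample 2 (−0.13 without sample 1), neuron markers −0.27 in sample 2 (−0.0708 without sample 1) and red blood cell markers 0.69 in sample 1 (0.39 without sample 3). Mast cell, hepatocyte, olfactory receptor and keratin-associated protein lists lay inside the central 95% of random lists in every sample. Of 12083 probe sets unnamed here, 4518 were above the limit on all arrays.

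In the following 3 patterns, the comparisons with scaling and with cell type lists were chosen after the result was seen, the former in place of quantile normalization, which moved a probe set by at most 0.134. The comparison with scaling used the same list values that raised the first 2 patterns, so it tests whether other genes of like level moved with them and adds no support for the patterns. The comparison with cell types was split by list after a combined value had been seen. The further gene lists were written before their values were computed, although single members had been seen in a ranking before the test. Taking the second lists over all measured members was also chosen after seeing the data. With 1 group in the labels, the design gives no biological explanation to set against these.

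The epidermis list exceeded the mean of the other samples by 5.78 in sample 2 (43.0-fold with levels under the limit set to the limit). Array-wide scaling would move genes of like level alike, but the central 95% of random lists of like level was −0.25 to 0.22, with the list 5.55 above its upper end, which argues against scaling as the whole cause. Skin in the specimen may be the source. A second list of barrier genes had a median excess of 1.29, positive for 17 of 17 genes above background on at least 1 array. DSC1 was at 10.55 and FLG2 at 9.73 in sample 2. Sample 2 alone decided this filter for some of the genes, such as FLG2 and CASP14. Over all measured barrier genes the excess was 1.28, positive for 17 of 18, and 0.90 with levels at the limit. Markers of Langerhans cells, the antigen-presenting cells of the epidermis, had an excess of 1.12 over the 3 genes above background on at least 1 array, a filter that sample 2 alone decided for CD207 and CD1A, and of 0.98 over all 5 measured, where CD1B and CD1C stayed below the limit. With levels at the limit the medians over 17 and 3 genes were 0.96, below the 1 set for the barrier list, and 0.85, and 6 of the 18 measured barrier genes were above background in all 3 samples, such as KLK5, at 7.11, 7.33 and 7.24.

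The skeletal muscle list exceeded the mean of the other samples by 1.22 in sample 1, where the central 95% of random lists of like level was −0.41 to 0.36, so that it lay 0.858 above the upper end, which argues against array-wide scaling as the whole cause, although with levels at the limit the margin was 0.518, close to the 0.5 set after the result was seen. Muscle fibres in the specimen may be the source, since a second list had a median excess of 1.04, positive for 12 of 13 genes. NEB was at 7.84 and SLN at 7.54 in sample 1, which alone decided the filter of at least 1 array for both. Over all 15 measured members the excess was 1.22, positive for 14, and 0.70 with levels at the limit. With levels at the limit the median over the 13 genes was 0.72, below the 1 set for this test. Of 15 measured members, 7 were above background in all 3 samples, and MYBPC1 went the other way, at 7.74, 7.18 and 9.24. MYL2, outside both lists and chosen after its value was seen, was at 7.92 in sample 1 and below the limit in the others.

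In sample 3 the steroid and growth hormone response list lay −0.98 and the immediate early genes −1.81 from the mean of the other samples, with 2 of 8 and 0 of 11 members above it. Clock genes formed a limb here called evening (7 genes, among them PER2) and an opposite limb (5 genes, among them BMAL1). A time of day that lowers the evening limb and raises the opposite limb is argued against. Opposite minus evening was −0.232 with a spread of 0.638, where over 1 was required. Other shifts in time were not tested, so another time of day in general stays open. Fewer cells of the adipocyte, endothelial and macrophage lists may account for the hormone response list. That list lay 0.283 above the lowest of these cell type lists (macrophages, −1.27), with a spread of 0.499. The hormone response list was level with blood endothelium (−0.99) and lower than adipocytes (−0.90). Immediate early genes lay −0.546 from the macrophage list, just beyond a spread of 0.473. The value also passed the bound of 0.5, set after the result was seen, for arguing against fewer cells. Without sample 2, however, immediate early genes deviated in sample 3 by −0.41 from the mean of the remaining pair, against −0.75 for macrophages. For immediate early genes fewer cells thus cannot be told apart from other causes. Less glucocorticoid signal also stays open: a second list of induced genes had a median of −1.20, with 0 of 10 positive and KLF9 at 9.63, 9.57 and 7.95, while TAT, also a glucocorticoid-induced gene, was highest in sample 3 (5.93, 7.75 and 9.59). Without sample 2 the deviations of sample 3 from the pair's mean were −0.41 for immediate early genes and −0.12 for adipocyte markers. The hormone response list, however, had −0.61, and −0.38 without sample 1, where macrophages had −0.52, blood endothelium −0.47 and hypoxia −0.43. A pair's mean includes sample 3, so these values are smaller in size than differences from the other sample. They cannot be set against −0.98 and −1.81.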
